A study of Caenorhabditis elegans with 12 samples.

How the data were processed

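Gene expression was measured by RNA sequencing in wild-type N2 Caenorhabditis elegans fed bacteria carrying control, vha-6, vha-16 or vha-19 RNAi, with 3 libraries per treatment and 12 in all. Per the labels, RNAi was begun at the L1 larval stage, the food of the vha groups held 25% target bacteria and 75% control bacteria, and whole worms were collected at the L4 to young adult stage after 2.5 days at 20 °C. Libraries were polyA-enriched and sequenced on the BGISeq500 platform. The deposited table holds raw read counts per gene, as the values are whole numbers whose column totals differ, and it carries no normalization. The submitters' processing notes name STAR 2.73a, edgeR 3.24.3 and the WBcel235/ce11 genome. The program that counted the reads, the strand setting and the rule of the gene filter named in the table are not given in the sources used here. The table holds 18467 genes and 3 further entries of unassigned reads, which were kept apart from the genes. Counts assigned to genes ranged from 21981854 to 22553227 per library.

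Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr with the treatment as group, which left 17043 genes and removed 1424. Libraries were scaled by the trimmed mean of M-values (TMM), whose mean factors were 0.770 in control, 1.05 under vha-6 RNAi, 1.10 under vha-16 RNAi and 1.12 under vha-19 RNAi. A negative binomial model with 1 mean per treatment was fitted to all 12 libraries, and 6 contrasts between pairs of treatments were tested with edgeR's quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method over the genes of each contrast, and genes with adjusted p under 0.05 were called. Calls with a change of 2-fold or more were also counted. A test with all 4 treatments at once, and the genes called in the same direction in all 3 comparisons with control, completed the set. Read counts scaled to a common library size (CPM) were computed on the TMM-scaled library sizes and are given as mean ± SD over 3 libraries. Log2 fold changes are given with their standard error (SE) where an error is shown. Gene symbols are those of the table. Of its genes, 17447 were matched to current names, 1368 of which differ from the table's, and positions were taken from Ensembl release 115 for 16935 genes.

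There were 30 gene lists, covering lysosome, stress responses, metabolism, tissues and developmental stage, written before the data were examined, as were the tests, the alternatives and the rule for naming genes. Each list was tested in the 6 contrasts with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and the 180 p-values were adjusted together. Camera asks whether a list moved relative to the other genes. It was repeated with a correlation estimated from the data, and fry, which asks whether a list's genes move on balance in 1 direction, was run beside it. Camera with the preset correlation called 114 of the 180 tests, fry called 165, and camera with the estimated correlation called 6.

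Genes are named by rule. For each comparison with control these are the 3 targeted genes, the 10 largest rises and 10 largest falls among called genes whose libraries did not overlap between the groups and whose mean was at least 5 CPM, and up to 4 members of each list with the smallest p. For comparisons between vha treatments the rule took the 6 largest in each direction and up to 3 members of each list, and for shared changes the 8 genes in each direction whose smallest change was largest. Any other gene named was chosen after its values were seen, and the text says so.

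The method was tested on simulated counts with the size and spread of these libraries. In the simulated vha-6 comparison with 15826 genes, 20 of 50 genes changed by 1.2-fold were called, 41 of 50 at 1.5-fold, 49 of 50 at 2-fold and 50 of 50 at 4-fold, with 8 false calls among 168 calls. A planted list made only of raised genes was called and 0 of 29 random lists of unchanged genes were, with genes drawn independently. Only these genes were changed, as many up as down. In the data at least 89.4% of genes were called in each comparison with control. The simulation therefore does not test TMM scaling, or the list tests, under such wide changes. Alternatives were DESeq2's size factors, library totals without TMM, TMM computed without genes of developmental stage, no filter on low counts, a filter at a mean of 5 CPM, counts thinned to the smallest library, the replicate number as a block, a fit to the compared groups alone, limma-voom, the Wald test of DESeq2 1.42.0, a 2-fold threshold, other list tests, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

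P-values measure only the spread between these samples, which may be technical. The labels do not say whether the replicates were separate cultures, and the biological coefficient of variation was 2.99%. Within groups the counts varied by 1.52 to 2.92 times what counting error alone gives (chi-square per degree of freedom), against 453 to 486 times between control replicate 1 and replicate 1 of each vha treatment, the pairs of different groups that were compared. Intervals on ratios with very low counts are 95% intervals and cover counting error only. With an unstated strand setting, genes that overlap on opposite strands are uncertain, and so are near-identical gene copies, whose reads can be shared or discarded.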

Results

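RNA from whole worms was compared between control RNAi and knockdown of 1 of 3 subunits of the vacuolar H+-ATPase (V-ATPase), the proton pump that acidifies lysosomes. The targets were vha-6, an intestinal subunit of the membrane sector, vha-16, the d subunit of the same sector, and vha-19, an accessory subunit. The series title names a surveillance response to lysosomal stress. The comparisons ask which transcripts change when each subunit is depleted. Each of the 12 libraries held 21981854 to 22553227 counts in genes. Libraries of a treatment lay close together. The first principal component of log2 CPM held 77.9% of the variance. It placed the controls between -165.62 and -164.1, vha-6 RNAi between 30.94 and 32.1, and the other treatments between 65.98 and 68.11. The second held 17.2% of it, and placed vha-6 RNAi between -77.24 and -76.85 and all other libraries between 11.33 and 35.41.

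The vha-6 transcript fell in all 3 knockdowns, while vha-16 and vha-19 fell under vha-16 and vha-19 RNAi and rose under vha-6 RNAi. The vha-6 gene (WBGene00006915, chromosome II, 11435210 to 11438452) stood at 401 ± 4.78 CPM in control and 93.7 ± 4.68 CPM under vha-6 RNAi (SD, n = 3 each), 23.4% of control (log2 fold change -2.1, SE 0.0358, adjusted p = 9.27e-33). It stood at 127 ± 0.946 CPM under vha-16 RNAi (log2 fold change -1.66, adjusted p = 2.19e-30) and 116 ± 2.66 CPM under vha-19 RNAi (-1.79, adjusted p = 2.76e-31). The vha-16 gene (WBGene00016258, chromosome I, 5079910 to 5082279) stood at 441 ± 12.1 CPM in control and 269 ± 7.06 CPM under its own RNAi, 61% of control (-0.71, adjusted p = 2.71e-20), but -0.19 when libraries are scaled by their totals. Under vha-6 RNAi it reached 871 ± 22.3 CPM (0.98, adjusted p = 1.55e-24). Under vha-19 RNAi it was 379 ± 6.69 CPM (-0.22, adjusted p = 1.74e-07), a fall that turns to 0.32 with library totals and is -0.039 with the filter at a mean of 5 CPM (adjusted p = 0.251). The vha-19 gene (WBGene00021952, chromosome IV, 3369197 to 3373485) stood at 470 ± 6.82 CPM in control, 217 CPM under its own RNAi (46.3% of control, -1.11, adjusted p = 1.3e-25) and 782 ± 14.6 CPM under vha-6 RNAi (0.74, adjusted p = 9.27e-21). Under vha-16 RNAi it was 318 ± 3.58 CPM (-0.56, adjusted p = 3.12e-17), but -0.042 with library totals (adjusted p = 0.222). With library totals vha-6 under its own RNAi is -1.65 and vha-19 under its own RNAi -0.57. Each of the 3 genes was lowest in the 3 libraries of its own RNAi.

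**Figure D1:**
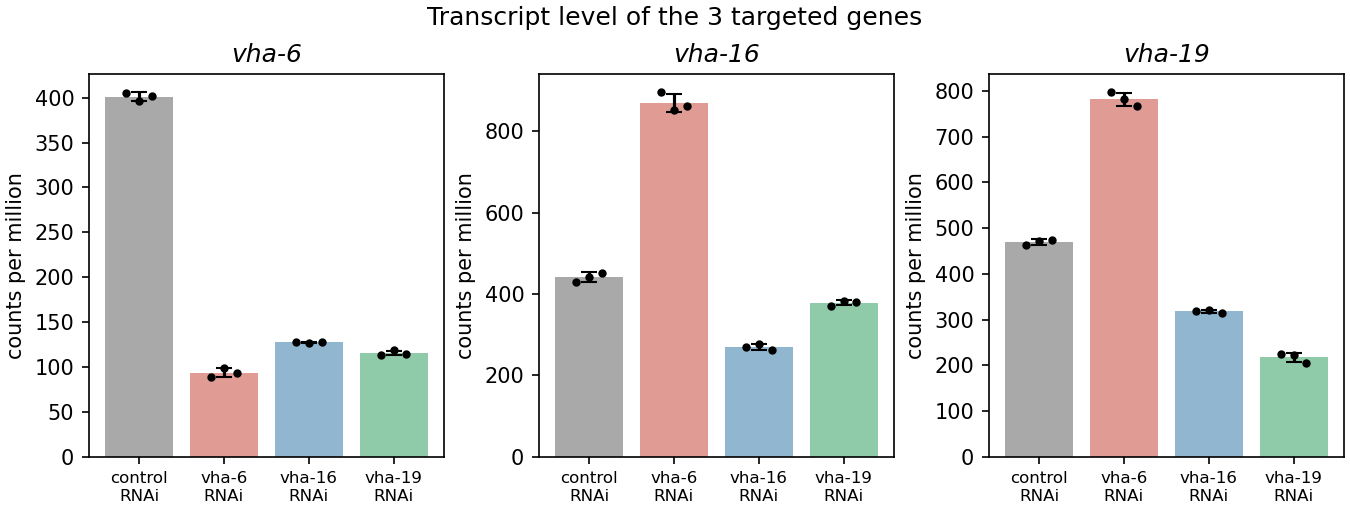
Transcript level of vha-6, vha-16 and vha-19 in CPM (vertical axis) under the 4 RNAi treatments (horizontal axis); bars are means, error bars the SD of 3 libraries, and dots the libraries. The vha-6 transcript is 401 in control and between 93.7 and 127 in the 3 knockdowns, while vha-16 and vha-19 are highest under vha-6 RNAi, at 871 and 782.

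Under vha-6 RNAi compared with control, transcripts of V-ATPase subunits and lysosomal proteases rose, and yolk protein, oocyte and proteasome transcripts fell. Of 22 V-ATPase genes, 18 rose and 4 fell (median log2 fold change 0.75), among them vha-12, from 670 to 1369 ± 25.9 CPM (log2 fold change 1.03), and vha-15 (1.07), while vha-18 fell (-1.39). Of 34 lysosomal proteases, 25 rose, 21 of them by 2-fold or more, and 9 fell (median 1.52). The cathepsin B-like cpr-4 rose from 312 ± 6.68 to 2961 ± 43.4 CPM (3.25). The aspartyl proteases asp-12 (5.4), asp-10 (current symbol hrg-7, 4.16) and asp-6 (2.47) rose as well. The list calls of both groups (adjusted p = 0.00986 and 0.0061) are lost with adjusted p = 0.289 and adjusted p = 0.158 with an estimated correlation. The heme-responsive gene hrg-2 rose from 1.36 ± 0.213 to 242 ± 4.4 CPM (7.47, SE 0.0754, adjusted p = 6.98e-39) and hrg-3, which encodes a carrier of heme from the intestine, from 1.69 ± 0.333 to 248 ± 4.92 CPM (7.19). The list of iron and metal genes was not called (adjusted p = 0.553).

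The largest rises under vha-6 RNAi included the C-type lectin genes clec-9 (2828-fold by pooled counts, 95% counting interval 782.5 to 23350, on 2 control counts) and clec-45 (895-fold, 247.5 to 7396, on 2 control counts). The glucuronosyltransferase gene ugt-18 reached 275 ± 4.88 CPM from 0.473 ± 0.158 CPM (log2 fold change 9.17), and the enoyl-CoA hydratase gene ech-9 reached 510 ± 34.6 CPM from 1.5 ± 0.302 CPM (8.41). F58E6.8 (8.44), T22F3.11 (8.06) and F46C5.1 (7.11) were also among them. The largest falls were pud-3 (-9.34) and pud-4 (-8.57), which are near-identical copies and so uncertain. Next came the yolk protein genes vit-4 (-9.20), vit-3 (-8.26), vit-1 (-7.11) and vit-5 (-6.81), of which vit-3, vit-4 and vit-5 are close copies of each other. skr-7 (-8.44), sea-1 (-6.97), clec-266 (-6.81) and btb-6 (-6.81) followed.

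Reproductive transcripts moved apart under vha-6 RNAi. All 6 vitellogenin genes fell (median -6.96). Their share of gene counts was 8.04% ± 0.124 in control and 0.961% ± 0.0571 under vha-6 RNAi (SD, n = 3). Of 61 oocyte and germline genes, 59 fell and 2 rose (median -2.51). The gene oma-2, which encodes an oocyte RNA-binding protein, went from 749 ± 15.7 to 34.9 ± 0.805 CPM (-4.43). Falls were also seen in pos-1 (-4.25), puf-5 (-3.83) and the yolk receptor gene rme-2 (-3.72). Of 104 sperm genes, 93 rose and 8 fell (median 1.29), with spe-41 at 2.07 and the sperm phosphatase gene gsp-3 at 2.13. The oocyte, vitellogenin and sperm calls have adjusted p = 0.0529, adjusted p = 0.186 and adjusted p = 0.0631 with an estimated correlation. Of 164 cuticle collagens 121 rose and 33 fell (median 2.17; col-71 3.76, col-77 3.86). Of 56 moulting genes 46 rose and 8 fell (median 1.62; grl-16 4.04, mlt-10 2.37). The collagen and moulting calls have adjusted p = 0.221 and adjusted p = 0.194 with an estimated correlation.

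All 31 proteasome genes fell under vha-6 RNAi, 28 by 2-fold or more (median -1.36; rpn-9 -1.66, pas-5 -1.76; adjusted p = 0.0529 with an estimated correlation). Of 72 oxidative phosphorylation genes 64 fell and 4 rose (median -0.47, but -0.022 with library totals; asb-1 -1.55). Of 82 cytosolic ribosomal protein genes 78 fell and 4 rose (median -0.47, but -0.019 with library totals; rpl-11.1 -1.24). The calls have adjusted p = 0.12 and adjusted p = 0.341 with an estimated correlation. Of 28 autophagy genes 21 fell and 6 rose (median -0.78; adjusted p = 0.0684 with an estimated correlation). In it the receptor gene sqst-1 rose (2.27) and epg-2 fell (-2.06). Library totals moved changes in this comparison by a median of 0.45, a large part of that autophagy median. In the mitochondrial unfolded protein response 15 of 22 fell and 7 rose (median -0.47, but -0.022 with library totals; the chaperone gene hsp-60 -1.72; adjusted p = 0.25 with an estimated correlation). In fatty acid metabolism 46 of 69 fell and 21 rose (median -0.41, but 0.04 with library totals; the desaturase gene fat-7 -4.27; adjusted p = 0.116 with an estimated correlation).

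Under vha-6 RNAi 104 of 171 C-type lectins rose by 2-fold or more and 18 fell as much (median 1.51; clec-67 4.36; adjusted p = 0.0529 with an estimated correlation). Of 62 innate immune effectors 43 rose and 14 fell (median 1.1; the saposin-like spp-2 4.01, the lysozyme gene ilys-5 -3.24). Of 41 genes of the intracellular pathogen response 32 rose and 2 fell (median 1.34; skr-3 1.82). These calls have adjusted p = 0.176 and adjusted p = 0.0684 with an estimated correlation. Of 60 neuronal markers 48 rose and 6 fell (median 0.94; egl-3 1.39, the tyrosine decarboxylase gene tdc-1 -2.76; adjusted p = 0.0559 with an estimated correlation).

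For the remaining 13 lists the list test was not called under vha-6 RNAi. Members that rose and fell numbered 32 and 19 of 57 other lysosomal genes (the acid ceramidase gene asah-1 2.45, the acid sphingomyelinase gene asm-3 -5.80), 13 and 12 of 27 in the endoplasmic reticulum unfolded protein response, and 6 and 10 of 18 in the heat-shock response (hsp-110 -1.36). They numbered 11 and 18 of 33 in oxidative stress defence, 18 and 11 of 32 insulin and DAF-16 genes (the noncoding RNA tts-1 5.19), 16 and 12 of 31 iron and metal genes, and 14 and 6 of 20 hypoxia genes (cysl-2 2.39). They numbered 102 and 56 of 194 detoxification genes (gsto-1 5.73), 21 and 11 of 34 intestinal markers (asp-3 2.61, cpr-6 -2.03), and 31 and 9 of 48 body-wall muscle markers (myo-3 1.71). They numbered 16 and 12 of 30 hypodermal markers (rol-6 3.87), 9 and 19 of 28 lysosomal signalling genes (the transcription factor gene pqm-1 2.47), and 14 and 26 of 43 amino acid and one-carbon enzymes (the glutamine synthetase gene gln-5 -3.79).

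In this comparison 8169 genes were called higher and 7059 lower, 5453 and 3872 of them by 2-fold or more. Adjusted over the list alone, the counts of rises and falls were the same in all 30 lists. With library totals in place of TMM the median of all genes moves by 0.45, the share of called genes that are higher goes from 53.6% to 63.9%, and the calls of 2-fold or more become 7296 higher and 2128 lower. DESeq2's size factors move the median by -0.14, and give 4917 higher and 4470 lower.

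Under vha-16 RNAi compared with control, V-ATPase, yolk, oocyte and oxidative phosphorylation transcripts fell, and rab-11.2, spp-20 and arf-1.1 were among the largest rises. Of 22 V-ATPase genes 21 fell and 1 rose (median -0.64, but -0.12 with library totals; vha-7 -1.84, vha-12 -0.92; adjusted p = 0.13 with an estimated correlation). The GTPase gene rab-11.2 rose from 0.475 ± 0.415 to 257 ± 8.99 CPM (log2 fold change 9.07, SE 0.102, adjusted p = 6.67e-38). arf-1.1 (current symbol warf-1) rose from 1.81 ± 0.752 to 783 ± 27.8 CPM (8.75). The saposin-like genes spp-20 (8.86) and spp-21 (356-fold by pooled counts, counting interval 98.25 to 2942, on 2 control counts) rose as well. So did F33H12.7 (8.33), F22E5.6 (8.34) and sdz-35 (8.01). The largest falls were pud-3 (-11.76), pud-4 (-10.72), vit-3 (-9.74), vit-4 (-9.63), the desaturase gene fat-7 (-8.55), skr-7 (-8.52) and acdh-2 (-8.51), with the copies named above uncertain here too.

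Lysosomal proteases went both ways under vha-16 RNAi. Of 34, 14 rose and 18 fell, with a median of -0.35 that turns to 0.10 with library totals, and the list was not called. The cathepsin B-like cpr-1 went from 791 ± 19.4 to 55.1 ± 2.04 CPM (-3.84) and asp-13 fell (-7.36), while cpr-3 rose (5.98). Other lysosomal genes were also not called as a list (19 rose and 31 fell of 57), with the lipase gene lipl-5 at -2.91 and gba-4 at -6.11; their median of -0.47 turns to 0.05 with library totals. The autophagy receptor gene sqst-1 rose from 63.6 ± 4.63 to 1279 ± 9.03 CPM (4.33) and lgg-1 rose (1.46), in a list with 12 rises and 14 falls of 28 that was not called. Its median of -0.09 turns to 0.43 with library totals, while its mean was 0.01. The intracellular pathogen response rose in 35 of 41 genes (median 2.47; skr-5 5.88, the cullin gene cul-6 2.91; adjusted p = 0.0529 with an estimated correlation). Innate immune effectors, with 21 rises and 35 falls of 62 (median -0.72), were not called as a list (adjusted p = 0.115). In the endoplasmic reticulum unfolded protein response 19 of 27 rose (median 0.76; the chaperone genes hsp-4 1.49 and enpl-1 1.09; adjusted p = 0.336 with an estimated correlation).

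Vitellogenins fell in all 6 genes (median -8.32; vit-6 -4.35) and took 0.580% ± 0.0284 of gene counts. Oocyte and germline genes fell in 58 of 61 (median -2.64; the eggshell gene cbd-1 -3.75, the chitin synthase gene chs-1 -4.35), and 90 of 104 sperm genes rose (median 1.21; spch-1 2.03). These calls have adjusted p = 0.185, adjusted p = 0.0529 and adjusted p = 0.0695 with an estimated correlation. Of 164 collagens 102 rose and 47 fell (col-113 5.62, col-101 -4.44), and of 56 moulting genes 47 rose and 6 fell (grl-21 5.25). The calls have adjusted p = 0.479 and adjusted p = 0.185 with an estimated correlation. Oxidative phosphorylation genes fell in 71 of 72 (median -1.15; the ATP synthase gene atp-2 -1.5), fatty acid genes in 51 of 69 (median -0.73; acdh-1 -5.79) and proteasome genes in 31 of 31 (median -0.95; pas-4 -1.39). Here the calls have adjusted p = 0.0529, adjusted p = 0.0529 and adjusted p = 0.0684 with an estimated correlation. The mitochondrial chaperone genes hsp-60 (-3.22) and hsp-6 (-1.61) fell, in a list with 20 falls of 22 (adjusted p = 0.0638 with an estimated correlation). Neuronal markers rose in 48 of 60 (unc-64 2.03; adjusted p = 0.0529 with an estimated correlation), and amino acid and one-carbon enzymes fell in 35 of 43 (mel-32 -2.15; adjusted p = 0.153 with an estimated correlation). Body-wall muscle markers fell in 30 of 48 and ribosomal protein genes in 78 of 82, with medians of -0.36 and -0.46 that turn to 0.16 and 0.06 with library totals. These muscle and ribosomal calls have adjusted p = 0.26 and adjusted p = 0.351 with an estimated correlation. Oxidative stress defence fell in 22 of 33 (median -0.55; adjusted p = 0.154 with an estimated correlation). Of lists not called, the heat-shock response had a median of -0.42 and a mean of 0.31, iron and metal genes -0.02 and 0.11, and C-type lectins 0.20 and -0.13, each with the test's direction down. With library totals the medians of oxidative phosphorylation, proteasome, mitochondrial stress and amino acid genes shrink to -0.63, -0.43, -0.31 and -0.37. Library totals moved changes in this comparison by a median of 0.52. That shift is nearly all of the -0.55 median of oxidative stress defence and most of the -0.73 median of fatty acid genes.

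Under vha-16 RNAi 8176 genes were higher and 7137 lower, 5845 and 4219 of them by 2-fold or more. With library totals the median of all genes moves by 0.52, the share that is higher goes from 53.4% to 65.2%, and the 2-fold calls become 7627 and 2353. DESeq2's size factors move the median by -0.19, and give a share of 49.5% and 2-fold calls of 5188 higher and 4957 lower. Adjusted over the list alone, the counts were the same in 28 of the 30 lists and differed by at most 1 gene in the others.

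Under vha-19 RNAi compared with control, the same named genes led both directions as under vha-16 RNAi in most cases. The largest rises included rab-11.2 (9.23), arf-1.1 (8.71), Y37H2A.11 (8.81), F22E5.6 (8.38), spp-20 (8.32), F33H12.7 (8.32), the tetraspanin gene tsp-1 (8.12) and Y41C4A.11. The last reached 5560 ± 148 CPM from 20.4 ± 7.66 CPM (8.09, SE 0.0917, adjusted p = 7.28e-38). Falls were led by pud-3 (-10.06), vit-4 (-9.60), vit-3 (-9.49), pud-4 (-9.24), vit-5 (-8.65), acdh-2 (-8.37), cyp-25A1 (-8.05) and fat-7 (-8.02). V-ATPase genes fell in 21 of 22 (median -0.74, but -0.19 with library totals; vha-7 -1.64; adjusted p = 0.13 with an estimated correlation). Of 34 lysosomal proteases 15 rose and 18 fell, with a median of -0.22 that turns to 0.32 with library totals. In it cpr-1 was at -4.25, asp-13 at -7.90 and cpr-3 at 6.04, and the list was not called.

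The intracellular pathogen response rose in 33 of 41 genes under vha-19 RNAi (median 2.55; skr-5 5.58; adjusted p = 0.0529 with an estimated correlation). sqst-1 rose (4.07), and the small heat-shock gene hsp-17 rose from 20.1 ± 0.889 to 251 ± 7.67 CPM (3.64). The vitellogenin share of gene counts was 0.484% ± 0.0387, and all 6 genes fell (median -8.39). Of oocyte genes 58 of 61 fell (median -2.62; oma-2 -4.38), and 89 of 104 sperm genes rose (median 1.27; gsp-3 2.11). The 3 calls have adjusted p = 0.185, adjusted p = 0.0529 and adjusted p = 0.0684 with an estimated correlation. Collagens rose in 109 of 164 and moulting genes in 46 of 56 (adjusted p = 0.377 and adjusted p = 0.185 with an estimated correlation). Oxidative phosphorylation genes fell in 71 of 72 (median -1.11; sdha-2 -2.06) and proteasome genes in 31 of 31 (median -0.98; pas-4 -1.44), with adjusted p = 0.0529 and adjusted p = 0.0684 with an estimated correlation. Innate immune effectors, with 19 rises and 36 falls of 62 (lys-8 -3.09, hpo-6 4.07), were not called as a list (adjusted p = 0.0502). The endoplasmic reticulum unfolded protein response rose in 19 of 27 (median 0.50), neuronal markers in 47 of 60 (median 1.1005), and fatty acid genes fell in 52 of 69 (median -0.67; elo-6 -3.62), with adjusted p = 0.409, adjusted p = 0.0529 and adjusted p = 0.0529 with an estimated correlation. Ribosomal protein genes fell in 78 of 82 (median -0.59, but -0.046 with library totals), amino acid enzymes in 33 of 43 (gln-5 -3.27) and mitochondrial stress genes in 20 of 22 (hsp-60 -2.99). These have adjusted p = 0.327, adjusted p = 0.178 and adjusted p = 0.0684 with an estimated correlation. Muscle markers fell in 28 of 48 and oxidative stress genes in 20 of 33, with medians of -0.32 and -0.49 that turn to 0.23 and 0.05 with library totals (adjusted p = 0.316 and adjusted p = 0.154 with an estimated correlation). Median and mean differed in sign for C-type lectins (0.12 and -0.26), detoxification genes (0.02 and -0.12) and the heat-shock response (-0.40 and 0.23), none of them called. With library totals the medians of oxidative phosphorylation, proteasome, mitochondrial stress and amino acid genes become -0.56, -0.44, -0.25 and -0.21. Library totals moved changes in this comparison by a median of 0.54, which is most of the -0.67 median of fatty acid genes.

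Under vha-19 RNAi 8122 genes were higher and 7198 lower, 5722 and 4248 of them by 2-fold or more. With library totals the median of all genes moves by 0.54, the share that is higher goes from 53% to 65.3%, and the 2-fold calls become 7629 and 2251. DESeq2's size factors move the median by -0.17, and give a share of 49.4% and 2-fold calls of 5117 higher and 4919 lower. Adjusted over the list alone, the counts were the same in 29 of the 30 lists.

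**Figure D2:**
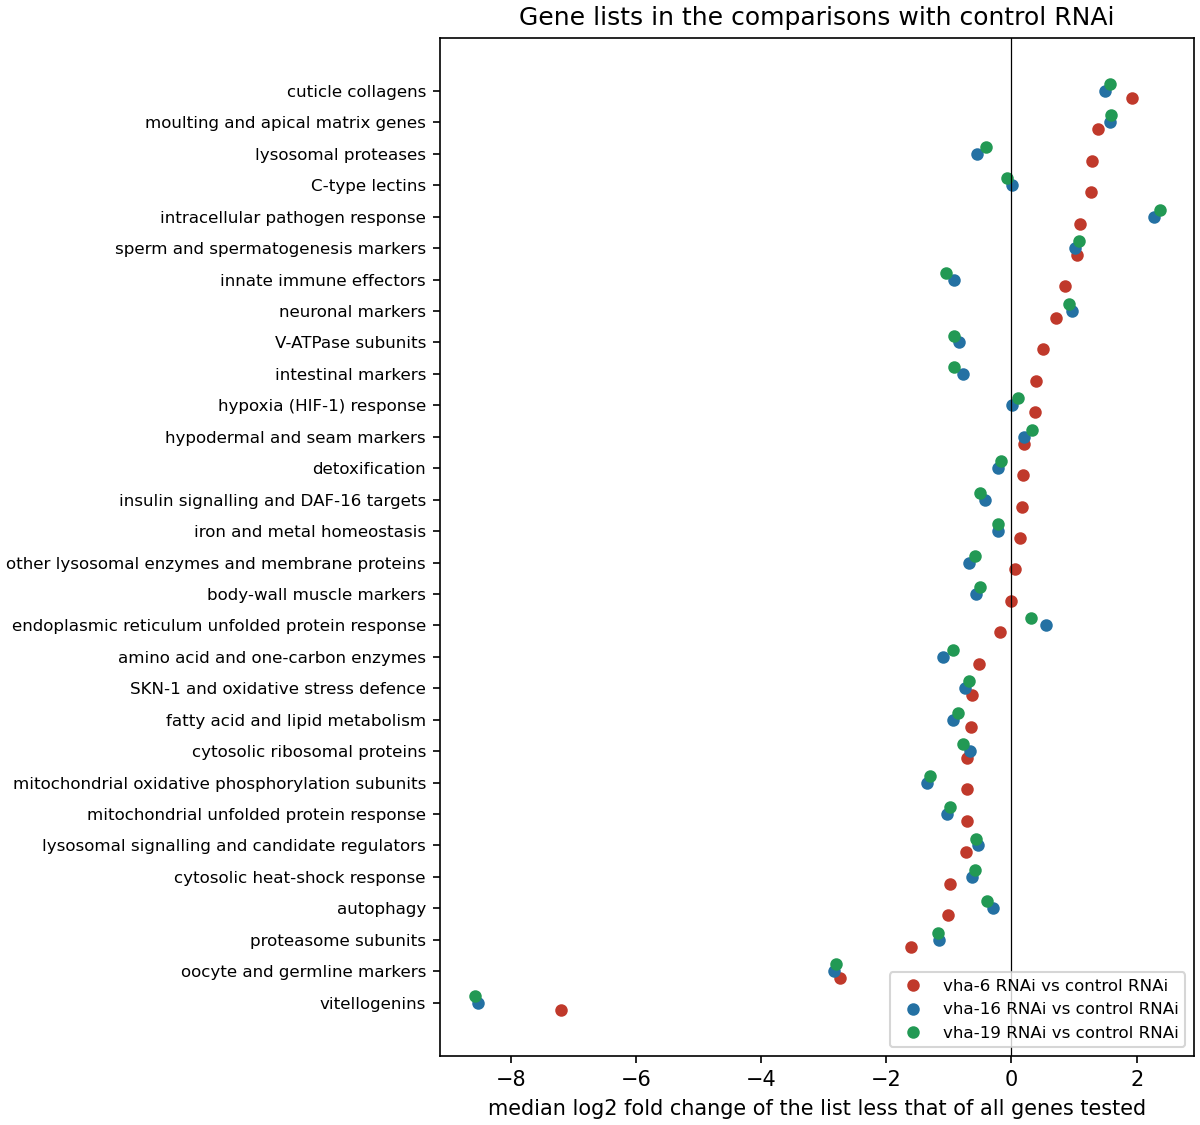
Median log2 fold change of each of the 30 gene lists less that of all genes tested (horizontal axis), in each comparison of a knockdown with control RNAi (points); the vertical axis names the lists. V-ATPase subunits lie at 0.51 under vha-6 RNAi, -0.84 under vha-16 RNAi and -0.92 under vha-19 RNAi, and vitellogenins lie lowest in all 3.

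Changes in the same direction in all 3 knockdowns were counted, since the subunits belong to 1 complex. The tetraspanin genes tsp-1 (6.11, 7.91 and 8.12 in the order vha-6, vha-16, vha-19) and tsp-2 (6.54, 7.17 and 7.20), hrg-2 (7.47, 5.72 and 6.29), T22F3.11 (8.06, 6.93 and 7.82) and C23G10.11 (6.65, 6.15 and 6.98) were among the genes with the largest shared rises. The largest shared falls were those of pud-3, pud-4, vit-1, vit-3, vit-4, vit-5, skr-7 and clec-266 (-6.81, -7.04 and -7.06). Called higher in all 3 were 6853 genes and lower 6225, with 4432 and 3136 changed by 2-fold or more in each. Independent lists of these sizes would share 1868 and 1248 genes, and 628 and 239 at 2-fold or more. In 20 simulated draws of 12 libraries with no differences, the same edgeR test gave means of 0.05 and 0 shared genes, and 39.7 and 33.2 at unadjusted p under 0.05. Across genes, which are not independent replicates, the fold changes correlated at 0.869 (vha-6 and vha-16), 0.875 (vha-6 and vha-19) and 0.988 (vha-16 and vha-19), where the shared control libraries alone gave 0.583, 0.585 and 0.591 in the simulation. The covariances were 3.09, 3.11 and 3.78 against 0.0163 simulated in each pair, an excess of 3.07, 3.09 and 3.76. The 3 controls cannot be split into separate sets, so a part of the excess that lies in how these controls were grown or handled cannot be removed.

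Compared with vha-16 RNAi, vha-6 RNAi gave higher lysosomal protease, V-ATPase, intestinal and C-type lectin transcripts and lower autophagy transcripts. Among lysosomal aspartyl proteases, asp-5 (3053 ± 21.2 against 133 ± 4.17 CPM, log2 fold change 4.52, SE 0.0368, adjusted p = 4e-41), asp-2 (4.70) and asp-1 (3.85) were higher. So were the acid ceramidase gene asah-1 (5.41) and gba-4 (6.94). Of 34 lysosomal proteases 24 were higher and 7 lower (median 2.22), and of 22 V-ATPase genes 18 were higher and 4 lower (median 1.25; vha-12 1.95, vha-13 1.67). The calls of these lists have adjusted p = 0.0529 and adjusted p = 0.0613 with an estimated correlation. Other lysosomal genes were higher in 31 of 57 and lower in 17 (median 0.26), and innate immune effectors higher in 46 of 62 and lower in 15 (median 1.65), with adjusted p = 0.0529 and adjusted p = 0.0529 with an estimated correlation. Intestinal markers were higher in 26 of 34 (median 0.58) and C-type lectins in 117 of 171 adjusted over the list alone (median 1.06; clec-169 6.45), and these calls hold with an estimated correlation (adjusted p = 0.0143 and adjusted p = 0.0216). Autophagy genes were lower in 26 of 28 and higher in 0 (median -0.78; sqst-1 -2.06, epg-9 -1.56), which also holds with an estimated correlation (adjusted p = 0.0143). The largest differences downwards were spp-20 (-8.15), Y37H2A.11 (-7.96), Y41C4A.11 (-7.79), F22E5.6 (-7.71), arrd-11 (-7.37) and rab-11.2 (-7.03). Upwards they were F58E6.8 (8.66), clec-9 (8.30), comt-2 (7.44), spp-4 (7.11) and ech-9 (6.82).

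Oxidative phosphorylation genes were higher under vha-6 than under vha-16 RNAi in 69 of 72 (median 0.61; atp-2 1.07), as were body-wall muscle markers in 39 of 48 (clik-1 1.61), and 44 of 164 collagens were higher by 2-fold or more (col-139 1.91), while the proteasome was lower in 31 of 31 (median -0.43; pbs-7 -0.76). These calls have adjusted p = 0.0529, adjusted p = 0.0529, adjusted p = 0.154 and adjusted p = 0.0529 with an estimated correlation. Genes of the intracellular pathogen response were lower in 28 of 41 (cul-6 -1.98) and of the endoplasmic reticulum unfolded protein response in 23 of 27 (ire-1 -1.38), with adjusted p = 0.0529 and adjusted p = 0.0684 with an estimated correlation. Called were 5313 genes higher and 5392 lower, 1260 and 1383 of them by 2-fold or more, and the share that is higher goes from 49.6% to 41.3% with library totals. Adjusted over the list alone, the counts were the same in 20 of the 30 lists and differed by at most 3 genes in the others. Sperm genes were not called as a list (31 higher and 23 lower of 104; median 0.06, but -0.012 with library totals).

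**Figure D3:**
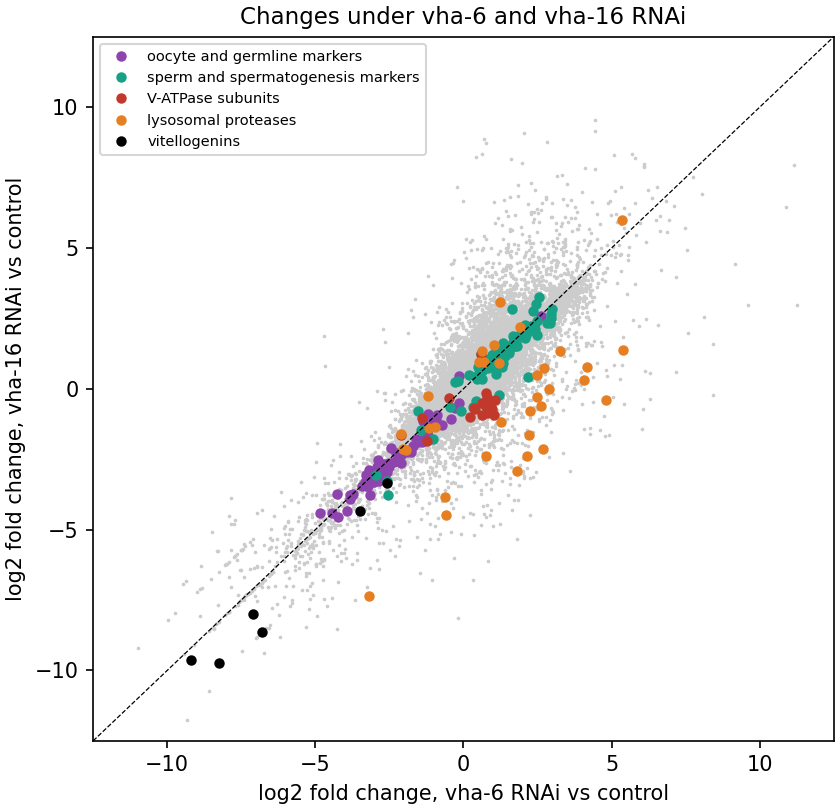
Log2 fold change against control RNAi under vha-6 RNAi (horizontal axis) and vha-16 RNAi (vertical axis); each grey point is a gene, coloured points are members of 5 gene lists, and the dashed line marks equal change. Across genes the correlation is 0.869; oocyte and vitellogenin genes lie low in both, and most V-ATPase genes lie to the right of and below the line, with medians of 0.75 and -0.64.

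Compared with vha-19 RNAi, vha-6 RNAi also gave higher lysosomal protease, V-ATPase, intestinal and C-type lectin transcripts and lower autophagy transcripts. asp-5 (4.74), asp-2 (4.88), asp-1 (4.07), asah-1 (5.68), gba-4 (6.91) and the lysozyme genes lys-4 (5.85) and lys-8 (600 ± 15.3 against 31.6 ± 1.44 CPM, 4.25) were higher. The genes sqst-1 (-1.80), hsp-17 (-1.98), hsp-16.48 (-4.06) and fpn-1.1 (-2.29), which encodes a ferroportin, were lower. Of 22 V-ATPase genes 18 were higher (median 1.19; adjusted p = 0.0554 with an estimated correlation) and of 34 lysosomal proteases 25 (median 2.29; adjusted p = 0.0529 with an estimated correlation). Autophagy genes were lower in 26 of 28, intestinal markers higher in 24 of 34 and C-type lectins higher in 108 of 171, which hold with an estimated correlation (adjusted p = 0.0143, adjusted p = 0.0143 and adjusted p = 0.0216). Ribosomal protein genes were higher in 54 of 82 (median 0.097; adjusted p = 0.53 with an estimated correlation), a list not called against vha-16 RNAi (16 higher and 16 lower; adjusted p = 0.939). Library totals moved changes between vha-6 and vha-19 RNAi by a median of -0.096, about the size of that ribosomal median, so this rise depends on the scaling. Insulin and DAF-16 genes were higher in 18 of 32 (adjusted p = 0.0214, but adjusted p = 0.0684 with an estimated correlation), and not called against vha-16 RNAi (adjusted p = 0.0604). Called were 4938 genes higher and 5021 lower, 1072 and 1191 of them by 2-fold or more, and the share that is higher goes from 49.6% to 36.5% with library totals. Adjusted over the list alone, the counts were the same in 18 of the 30 lists and differed by at most 2 genes in the others.

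vha-16 and vha-19 RNAi differed little from each other. The collagen gene col-113 (194 ± 4.89 against 72.7 ± 5.64 CPM, log2 fold change 1.42, SE 0.0422, adjusted p = 6.5e-23), the small heat-shock gene hsp-43 (1.13), the antimicrobial peptide gene cnc-4 (1.18), clec-42 (1.18), the metallothionein gene mtl-1 (1.13) and nas-10 (1.34) were higher under vha-16 RNAi. The genes col-179 (-1.07), cysl-2 (-0.80) and pck-1 (-0.54) were lower. Each target was lower under its own RNAi (vha-16 -0.49, vha-19 0.55). Cuticle collagens were lower in 78 of 164 and higher in 12 (median -0.19), ribosomal protein genes higher in 59 of 82 (median 0.11) and innate immune effectors higher in 26 of 62 (median 0.24). In this pair the calls have adjusted p = 0.11, adjusted p = 0.21 and adjusted p = 0.0529 with an estimated correlation. Adjusted over the list alone, the counts were the same in 8 of the 30 lists and differed by at most 10 genes in the others. In all 1672 genes were called higher and 1289 lower, 71 and 18 of them by 2-fold or more. The count of higher genes is 1059 with DESeq2's Wald test, 1105 without vha-16 replicate 1 and 1099 without vha-19 replicate 2. The share of calls that is higher goes from 56.5% to 44.8% with library totals and to 47.9% with DESeq2's size factors. It lies between 46.8% and 49.2% when 1 vha-16 or vha-19 library is left out. With limma-voom it is 57.1% and with the replicate number as a block 56.3%, so which direction has more calls depends on the processing.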

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

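In this part all tests of explanations were chosen after the result was seen, the criteria for scaling, for adult collagens, for a stage in between and for off-target silencing were rewritten after their values were known, and the count of splits was planned.

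Among reads not assigned to a gene, those that were ambiguous or in no annotated feature took a larger share in every knockdown library than in any control library. All unassigned reads together took a smaller share, 11.396%, 9.94% and 10.3% under vha-6, vha-16 and vha-19 against 16.8% in control, because fewer reads aligned to several places. Ambiguous reads made up 0.904% of all counted reads under vha-6 RNAi, 1.00146% under vha-16 RNAi and 0.986% under vha-19 RNAi, against 0.863% in control. Reads in no annotated feature made up 0.995%, 1.296% and 1.27%, against 0.693% in control.

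The first pattern is lower oocyte, germline and vitellogenin transcripts with higher moulting and collagen transcripts in all 3 knockdowns. Scaling is argued against: over 4 scalings and 3 comparisons the oocyte list's median log2 fold change stayed at -2.06 or lower, while scaling moved the median of all genes by at most 0.54. A smaller germline share of unchanged make-up is argued against as the whole cause, since sperm genes, also germline genes, lay at least 1.01 above the median of all genes. This does not speak to a germline at an earlier stage, whose mix of sperm and oocyte transcripts may differ. An earlier developmental stage of the knockdown animals may contribute and cannot be told apart from a direct effect of the RNAi. The median of 3 adult collagen genes less that of all genes was 1.93, 0.28 and 0.82 under vha-6, vha-16 and vha-19. Without that subtraction, col-19 fell in all 3 comparisons (-0.21, -1.72 and -0.94) while col-62 rose (2.55, 0.99 and 1.56). The -0.21 is smaller than the 0.45 by which library totals moved changes under vha-6 RNAi, so its direction depends on the scaling. The gene col-7 was at 2.16, 0.49 and 1.01, and was not called under vha-16 RNAi (edgeR adjusted p = 0.0652). These 3 collagen genes were chosen after the data were examined. The labels give 1 collection time for all groups, and a biological effect of V-ATPase loss on the germline stays open, untested.

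The second pattern is higher V-ATPase and lysosomal protease transcripts under vha-6 RNAi than under the other knockdowns. Scaling is argued against, since the lower of both list medians stayed at 1.09 or higher over 4 scalings and 2 comparisons. A stage under vha-6 RNAi between those of the control and the other knockdowns stays open. The criterion was that 17 of 22 V-ATPase genes were higher under vha-6 RNAi than in control and in both other knockdowns. It could speak against such a stage only if these genes change steadily with stage, which was not tested. The vitellogenin share of gene counts lay in between, at 0.961% under vha-6 RNAi. It was 8.04% in control, and 0.580% and 0.484% under vha-16 and vha-19 RNAi. A larger intestinal share of the RNA as the whole cause could not be excluded: both lists exceeded intestinal markers outside them, by 0.65 at the least, with bootstrap intervals over genes that include 0 (-0.29 to 1.03 in that case). That V-ATPase and protease genes respond to loss of vha-6 beyond any change in tissue share may be proposed as a hypothesis and stays open.

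The third pattern is the fall of vha-6 under vha-16 and vha-19 RNAi. A fall shared by all V-ATPase genes as the whole cause stays open: 1 of 19 subunit genes that were not targeted, vha-7 (-1.84), fell by as much as vha-6 under vha-16 RNAi and 0 did under vha-19 RNAi, where their median was -0.72. Off-target silencing of vha-6 as the whole cause stays open too: 9 of 33 intestinal markers outside the V-ATPase list fell by as much in each comparison, so a change among intestinal transcripts could include vha-6. Construct and genome sequences were not used here, so the overlap of the constructs with vha-6 was not tested.

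Other splits of the libraries were fitted in the same way with edgeR. For the 6 pairwise comparisons there are 10 splits each, too few for a share under 0.05. The real splits called 15228, 15313, 15320, 10705, 9959 and 2961 genes, and 1 split, the real one, reached each count; the highest of the other splits was 0 in each, and 92, 101, 104, 262, 328 and 1059 genes at unadjusted p under 0.05. For all 4 groups together 60 splits were used, the real one and others drawn at random from the many possible, so 1 of 60 is the smallest share that can be seen. In the test of 4 groups, 1 of 60 splits reached 16213 genes and the highest other gave 11942, a share under 0.05. For genes shared by the 3 knockdowns, 1 of 60 splits reached 6853 higher and 1 of 60 reached 6225 lower. The highest other was 0 in both, and 575 and 5 at unadjusted p under 0.05. Other splits mix treatments within a group, which widens the spread and lowers their calls of single genes. They cannot exclude chance differences between cultures, as the replicates may be technical. For the gene lists 8 of 60 splits, the real one included, called at least the real 114, with 124 as the highest other. These splits still hold treatment differences between their groups, so they do not show how many list tests chance alone would call. Chance is thus neither excluded nor shown for the number of called list tests.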

How the results depend on the processing

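The alternatives were planned before the data were examined. Of values for the named genes, 15409 kept their direction and side of the threshold, 26 lost the call, 2 gained it and 1 reversed. Most of these genes were named for large changes or small p in the same data, so they do not stand for all genes. Over all genes tested, library totals reversed the direction of 518 calls for vha-6 against control. They reversed 731 for vha-16 against control, 794 for vha-19 against control and 0 between knockdowns. DESeq2's size factors reversed 0, 21 and 11 against control, in the same order. Of list results 4022 were the same, 161 weaker and 107 stronger; of counts 352 stayed within 1.5 times the value reported and 15 moved. The reversed value among the named genes is vha-16 under vha-19 RNAi, 0.32 with library totals in place of TMM and -0.039 with the filter at a mean of 5 CPM. The value of vha-19 under vha-16 RNAi was -0.042 with library totals. The TMM factor of the controls is 0.770 and leaving it out raises all changes against control, which is the cause for library totals. With the CPM filter TMM was computed again on the genes kept. This moved changes under vha-19 RNAi against control by a median of 0.18, a shift that takes vha-16 from -0.22 to -0.039. The threshold of 2-fold lowered the counts by construction to 3872, 4219 and 4248 genes lower than control in the vha-6, vha-16 and vha-19 knockdowns. It gave 1260 higher and 1383 lower for vha-6 against vha-16, 1072 and 1191 for vha-6 against vha-19, 71 and 18 for vha-16 against vha-19, and 4432 and 3136 shared. Genes higher under vha-16 than vha-19 RNAi numbered 1059 with DESeq2 and 1099 to 1690 when 1 library was left out, with 1105 without vha-16 replicate 1 and 1099 without vha-19 replicate 2; the cause was not tested. Called list tests numbered 6 with an estimated correlation against 114, as lists whose genes vary together gain wider errors. With the replicate number as a block, vha-6 RNAi gave 8156 genes higher and 7060 lower than control. Of 18 pairs of libraries with the same number 0 correlated above 0.1 (-0.035 to 0.05), and 0 libraries matched their own number best in every other group. Between vha-16 and vha-19 RNAi, however, pairs of the same number correlated at 0.027, 0.028 and 0.05, and pairs of unlike numbers at -0.003 or lower. The numbers thus showed no pairing across all groups, while a weak pairing of these 2 treatments stays open. Depth was even, and thinning to the smallest library moved no count by over 1.5 times.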

Other observations

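In this part the families of gene names were chosen after the data were seen, and the test of X-linked genes was written before its result was seen.

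Name families showed further groups. Of 97 families with at least 15 members, tested with camera in the 6 comparisons, 38 of 582 tests were called with an estimated correlation. F-box genes of the fbxb family fell by 2-fold or more in 80 of 84 genes in each knockdown (median log2 fold change -5.41, -5.74 and -5.39). Camera gave adjusted p = 0.00218 with an estimated correlation in each. Sequences of the family were not compared here, and reads of any close copies in it are uncertain. Nuclear hormone receptor genes (nhr) rose in 147, 154 and 152 of 208 (median 0.76, 1.01 and 0.99; adjusted p = 0.00548, adjusted p = 0.00424 and adjusted p = 0.00469 with an estimated correlation), and the fbxa family rose in at least 111 of 175 (median 0.88, 1.41 and 1.37; adjusted p = 0.0341, adjusted p = 0.0322 and adjusted p = 0.0322 with an estimated correlation).

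Beside the fall of oocyte and germline markers in 58 or 59 of 61 genes, with medians of -2.51 to -2.64, smaller falls were seen in other families, and whether they are separate from it was not tested. Mediator subunit genes (mdt) fell in all 20 members in each knockdown (median -1.31, -1.19 and -1.2; adjusted p = 0.0322, adjusted p = 0.0341 and adjusted p = 0.0341 with an estimated correlation), and mitochondrial ribosomal genes (mrps) in 28 of 29 (median -1.09, -1.26 and -1.31; adjusted p = 0.0359, adjusted p = 0.0341 and adjusted p = 0.0341). The larger mitochondrial ribosomal family mrpl fell in 40, 39 and 40 of 40 (median -0.97, -1.17 and -1.21), a call lost under vha-6 RNAi with adjusted p = 0.055 with an estimated correlation and kept in the others (adjusted p = 0.0485 in each). Vacuolar sorting genes (vps) fell in 30 of 31 under vha-6 RNAi (median -0.81; adjusted p = 0.0322 with an estimated correlation), and were lower there than under vha-16 RNAi in 22 of 31 (median -0.39; adjusted p = 0.0341). Rab GTPase genes were lower under vha-6 than vha-16 RNAi in 17 of 20 (median -0.67; adjusted p = 0.0322), and the ugt family was higher in 39 of 63 (median 0.60; adjusted p = 0.0341). All 31 FMRFamide-like peptide genes (flp) rose in each knockdown (median 1.17, 1.55 and 1.45), calls that are lost with adjusted p = 0.147, adjusted p = 0.141 and adjusted p = 0.143 with an estimated correlation.

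Of genes changed by 2-fold or more, 92 were higher than control under vha-6 RNAi and lower under both other knockdowns, and 11 the reverse; 1017 rose and 821 fell in vha-16 and vha-19 RNAi and stayed under 2-fold or uncalled under vha-6 RNAi. The 15 mitochondrial genome genes took 0.909% ± 0.0212 of gene counts in control, 0.553% ± 0.00529 under vha-6 RNAi, 0.538% ± 0.0211 under vha-16 RNAi and 0.568% ± 0.0337 under vha-19 RNAi (SD, n = 3). Reads aligned to more than 1 place were 15.3% of all counted reads in control and 9.50%, 7.64% and 8.08% in the knockdowns.

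A hypothesis was that less oocyte and germline RNA, in which X-linked genes are under-represented, would leave X-linked genes higher than autosomal ones. The median of 2362 X-linked genes exceeded that of 14560 autosomal genes by 0.31, 0.39 and 0.35 in the vha-6, vha-16 and vha-19 knockdowns (lowest bootstrap bound over genes 0.23), above the 0.1 set beforehand. Less oocyte RNA could give this. Sperm genes lay at least 1.01 above all genes, which argues against a smaller germline share of unchanged make-up as the whole cause of the first pattern. That value does not test what raised X-linked above autosomal genes. A germline at an earlier stage, or a direct effect on X-linked genes, was not told apart and could give the same difference.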
